A study of Mus musculus with 4 samples.

How the data were processed

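ATAC-seq libraries of melb-a cells were compared between 2 control hairpins and 2 Hira hairpins, with 1 library per hairpin. Libraries were made with a commercial ATAC-seq kit, per the labels' protocols. The submitters' processing notes name cutadapt 2.3, Bowtie2, Picard, MACS2 2.2.9.1 and edgeR 3.38.4 and the mm10 build, without their roles. Whether duplicates, mitochondrial reads or blacklisted regions were removed, whether reads were shifted for the transposase, and how peaks of single libraries were merged is not given in the sources used here. Repeated copies of a sequence share reads that map to several places, and how these were handled is not given either.

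The deposited table holds 1 peak set for all libraries, with an annotation of each peak and its distance to the nearest TSS. Tags per peak and library are estimated counts as deposited by the authors: every value is a multiple of 0.5, and they were rounded to whole numbers before each count test. The authors also deposited a log2 fold change and a mean log2 CPM per peak, a likelihood ratio statistic (a score per peak, per the file headers), and p-values with their Benjamini-Hochberg adjustment. Their calls match an adjusted p under 0.01 with an absolute log2 fold change of at least 1 for all peaks. The scaling behind the authors' fold changes is not given in the sources used here. It was recovered by least squares from 46005 peaks with more than 30 tags in every library (residual SD 0.014 log2). The library sizes so obtained were 0.97, 1.07, 1.33 and 1.08 times the tags in peaks for controls 1 and 2 and hairpins I and II. Library sizes here are tags in peaks, so a change in the share of reads outside peaks would not be seen.

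Columns were matched to samples by name, the Hira columns by the numeral of the hairpin. The table names the Hira columns as knockouts and the labels describe knockdowns by hairpin. Total tags in peaks ranged from 8910983 to 20716859.5, so the precision of a peak is lowest under hairpin II.

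The test of each peak was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr, the group as the only term, and a two-sided Benjamini-Hochberg adjusted p under 0.05, which left 70429 peaks. Standard errors are the absolute log2 fold change over the square root of the F statistic. The log2 ratio of each hairpin to the summed controls used a prior of 2 tags. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were 12 genes of the lineage and the cell cycle at the peak nearest the TSS, the 10 largest changes per direction among peaks above the median abundance with both Hira libraries beyond both controls, and the 4 lowest p-values in each list that passed and in the pigment and melanoblast lists. Predicted genes and small RNA genes were left out of the largest changes. Some items that the rule names are not reported here. Any gene named for its count of peaks in the closing section was chosen after its values were seen.

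The 15 gene lists and 5 lists of markers of other cell types were tested with camera (limma 3.58.1) on log2 CPM of all peaks assigned to their genes, with a preset correlation of 0.01 and adjustment over the 20 lists. Of 457 listed genes 396 had a peak under the same symbol. A peak counts once per peak, so genes with many peaks weigh more. No list passed with an estimated correlation.

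Control libraries were compared by a chi-square of their tags over peaks with at least 20 tags in the pair, and by the biological coefficient of variation, which was 0.00988 for the controls and 0.236 for the Hira pair. The main fit kept them as 2 libraries, as fixed in advance. Its spread is therefore averaged over a pair with almost none and the Hira pair. Fits with the controls summed to 1 sample, with the authors' scaling, with edgeR's newer quasi-likelihood estimate, without rounding and with the column numbers as a replicate block were chosen after seeing the data. Other alternatives were DESeq2 1.42.0 (size factors, Wald test), limma-voom, the likelihood ratio test, cyclic loess offsets, total tags, filters, thresholds, autosomes and each library left out.

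The fit was tested on simulated data for the comparison of Hira with control, over 70436 peaks with a coefficient of variation of 0.15. It recovered 50 of 100 peaks changed by a log2 of 1 and 94 of 100 changed by a log2 of 2, with 10 false calls. The simulation gave all libraries the same coefficient and changed few peaks. In the data the coefficient was 0.00988 for the controls and 0.236 for the Hira pair, and 17840 of 70429 peaks were called. The count of false calls therefore does not carry over to the main fit. A motif test fixed in advance was not run, since no genome sequence was used here. Figures were drawn with matplotlib 3.10.9.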

Results

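Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in melb-a cells, a mouse melanoblast line (melanoblasts are the embryonic precursors of pigment cells). The cells carried lentiviral short hairpin RNAs and were selected with puromycin. The control arm held 2 libraries, with hairpins against luciferase (control 1) and of scrambled sequence (control 2). The Hira arm held 2 libraries with different hairpins against Hira (hairpins I and II), which encodes a chaperone that deposits the histone variant H3.3. The question was how knocking down Hira changed accessibility. The table covered 70436 peaks of the mm10 genome, with 20716859.5 and 15804532 tags in peaks for controls 1 and 2, and 14718721 and 8910983 for hairpins I and II. Median depth per peak ranged from 54 tags (hairpin II) to 126 tags (control 1).

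The control libraries differed by less than the sampling noise and were counted as 1 sample in every mean and n below. Their chi-square per peak was 0.933, and 1.02 in the 10% of peaks with the most tags, against 6.24 and 7.46 for the 2 Hira libraries. Values are given in CPM, tags scaled to the TMM-corrected library size, as the control level (n = 1) and the Hira mean ± SD (n = 2). Unless another fit is named, SEs and adjusted p-values below come from the fit that kept the controls as 2 libraries. They therefore do not match the n of the controls, and the calls depended on this choice, as given below. Each library carried its own hairpin, and no hairpin had a second library. The p-values therefore measure only the spread between these libraries, in which differences between hairpins, cultures and technical steps cannot be separated.

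Accessibility under both Hira hairpins differed from the controls in both directions across the genome. It did so at a smaller share of promoter peaks than of other peaks. Peaks that closed included those around the pigment genes Tyrp1, Tyr and Dct, and peaks that opened included those around extracellular matrix genes and the neural crest genes Snai1, Id2 and Ets1. In the edgeR quasi-likelihood fit to the 4 libraries, 17840 of 70429 tested peaks changed at an adjusted p under 0.05, 10127 higher and 7713 lower in Hira shRNA. The smallest adjusted p was 0.0125, shared by many peaks. This count rested on how the controls were treated: with the control libraries counted as 1 sample the same test called 0 peaks (15569 at an unadjusted p under 0.05, smallest adjusted p 0.0704), while edgeR's newer quasi-likelihood estimate called 9919 and its likelihood ratio test 8558. Without control 1 or control 2 the quasi-likelihood test called 0 peaks (15162 and 15189 at an unadjusted p under 0.05), without hairpin I 27887, and without hairpin II 42998. With a hairpin left out the spread comes from the control pair alone, so calls of peaks and lists in those fits set the other hairpin against technical noise and do not support a change.

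The balance of gains and losses depended on the scaling of the libraries. Under TMM factors 56.8% of the changed peaks were higher, and the median log2 fold change over all peaks was 0.0019. Under the scaling recovered from the authors' fold changes the median shifted to −0.26, and 36.9% of 21198 changed peaks were higher. The authors' deposited table itself calls 5970 peaks higher and 8291 lower, with a median log2 fold change of −0.25. Of these calls 5725 and 6402 were also called in the same direction here, and 0 in the opposite direction. All changes below are relative to the bulk of peaks.

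The 2 Hira hairpins moved many peaks in common. Hairpin I gave at least a 2-fold rise over the control at 10094 peaks and hairpin II at 6457, of which 5947 were shared, against 925 for independent lists. At least a 2-fold fall was seen at 9546 and 6099 peaks, with 4241 shared against 827 for independent lists, and 22 peaks went 2-fold in opposite directions. Across peaks, which are not independent replicates, the log2 ratios of the hairpins correlated with r = 0.826 and a covariance of 0.707. Unchanged libraries simulated against the same controls gave 0.226 and 0.0148. With control 1 used for hairpin I and control 2 for hairpin II, r was 0.797 and the covariance 0.669. This takes out only the sampling noise of a shared control, since the control libraries count as 1 sample. Any other difference between the arms could also move both hairpins alike, and these values cannot tell it from an effect of Hira. Hairpin I had the larger changes, with an SD of log2 ratios of 1.07 against 0.80, and lay further from the control at 78.5% of changed peaks.

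**Figure D1:**
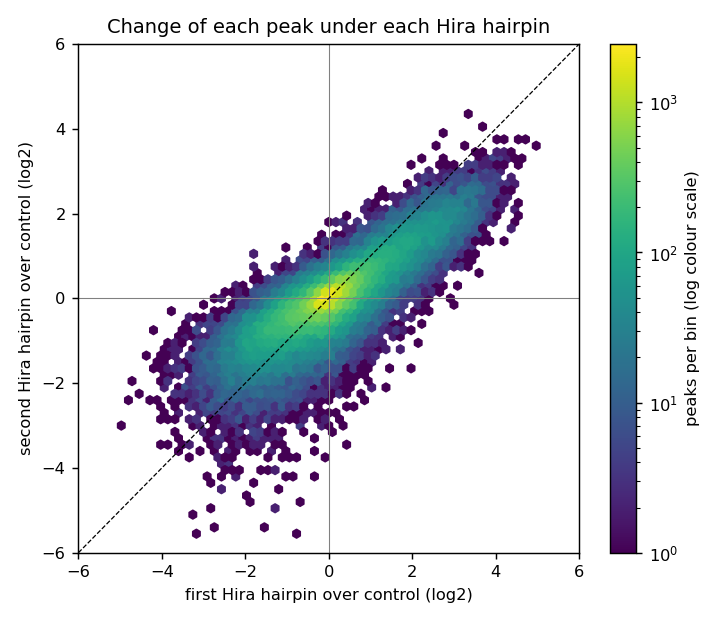
Log2 ratio to the pooled control for each tested peak under hairpin I (x axis) and hairpin II (y axis), with colour giving the number of peaks per bin on a log scale and the dashed line marking equal change. Peaks spread along a line flatter than the dashed one (r = 0.826), with the larger changes under hairpin I.

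Among the annotation classes, promoters and 5′ UTRs changed least often. Of 7588 tested promoter peaks 358 rose and 172 fell (6.99% changed), against 9769 and 7541 of 62841 peaks of the other classes (27.6% changed). In the 5′ UTR class 55 of 1039 peaks rose and 13 fell. Without any test, both hairpins lay at least 2-fold from the control, in the same direction, at 1.78% of promoter peaks and 16% of the others. The SD of log2 fold changes was 0.38 in promoter peaks and 0.97 elsewhere. The share changed increased with distance to the nearest transcription start site (TSS), from 7.45% within 1 kb to 33.2% beyond 100 kb. Gains and losses were distributed differently: 16.3% of peaks beyond 100 kb were higher and 17.0% lower, whereas within 1 kb 5.32% were higher and 2.14% lower. Among changed peaks, 67.6% of promoter peaks and 56.4% of the others were higher (odds ratio 1.61, 95% interval 1.33 to 1.94, two-sided Fisher's exact test across peaks, p = 2.82e-07). That difference in direction did not hold with scaling by total tags alone (odds ratio 1.04, Fisher's exact p = 0.642) and turned round without hairpin II (odds ratio 0.601).

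**Figure D2:**
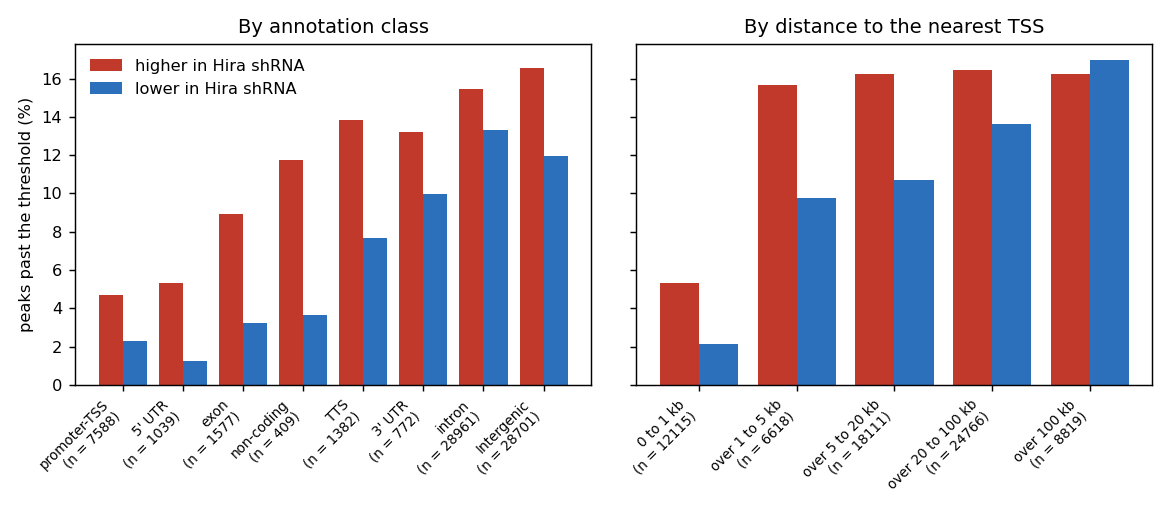
Percent of tested peaks called higher (red) or lower (blue) in Hira shRNA, by the authors' annotation class (left) and by distance to the nearest TSS (right), with the number of peaks under each label. Promoter and 5′ UTR peaks have the lowest bars on the left, and the blue bars grow with distance, from 2.14% within 1 kb to 17.0% beyond 100 kb.

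At the targeted gene, the Hira promoter peak (chromosome 16, 18876130 to 18877268) had 72.4 CPM in the controls and 68.0 ± 7.39 in Hira shRNA (log2 fold change −0.09, SE 0.09, edgeR adjusted p = 0.486). The value depended on the hairpin: −0.21 without hairpin II and 0.02 without hairpin I. A hairpin acts on the transcript, so accessibility of this promoter does not check the knockdown. Mitf is the master regulator of the melanocyte lineage, and Pax3 a transcription factor upstream of it. Their promoter peaks nearest a TSS gave log2 fold changes of 0.04 (SE 0.11, edgeR adjusted p = 0.8) and 0.13 (SE 0.07, adjusted p = 0.207). Under the authors' scaling both were negative, −0.20 and −0.13. The Mitf value changed sign with the hairpin, from 0.17 without hairpin I to −0.09 without hairpin II. Mitf has another annotated TSS, to which the intergenic Mitf peak given below was assigned. The promoter peak used here (chromosome 6, 97806618 to 97807630) therefore does not cover all Mitf promoters. The Sox10 promoter peak stood at 0.38 (SE 0.12, adjusted p = 0.0699), with 0.25 without hairpin I, 0.49 without hairpin II and 0.10 under the authors' scaling (adjusted p = 0.768). It passed in edgeR's likelihood ratio test (adjusted p = 0.0486) and limma-voom (0.049), but not in the DESeq2 Wald test (0.276), nor with the controls as 1 sample (edgeR quasi-likelihood, 0.395). The log2 fold change was −0.18 at the intronic Kit peak 0.459 kb from its TSS (SE 0.08, adjusted p = 0.159), with −0.25 without hairpin I, −0.12 without hairpin II and −0.44 under the authors' scaling. Neither Cdkn1a nor Cdkn2a, which encode inhibitors of the cell cycle, had a peak that passed the test. The Cdkn1a peak nearest the TSS gave 0.28 (SE 0.11, edgeR adjusted p = 0.112), with 0.41 without hairpin II, 0.12 without hairpin I and 0.01 under the authors' scaling (adjusted p = 0.99). The 1 peak assigned to Mlana, 15.7 kb from its TSS, had a log2 fold change of 0.06 (SE 0.46, adjusted p = 0.935; log2 fold change 0.68 without hairpin I and −0.67 without hairpin II), and no peak was assigned to Pmel.

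More peaks of pigment genes fell than rose. Of 142 tested peaks assigned to genes of pigment synthesis and the melanosome, 34 fell and 9 rose (37 and 11 adjusted over the list alone). Among its 24 genes with peaks, 12 had only falling peaks, 1 only rising peaks, 5 both and 6 neither. The list lay below other peaks by a mean log2 of 0.43 (camera, adjusted p = 0.000922 over 20 lists; adjusted p = 0.331 with an estimated correlation, and 0.0936 with 1 peak per gene). At Dct, which encodes dopachrome tautomerase of melanin synthesis, the promoter peak (chromosome 14, 118052006 to 118052994) fell from 41.4 CPM to 18.8 ± 6.39 (log2 fold change −1.16, SE 0.22, adjusted p = 0.0201). At Tyr, encoding tyrosinase, the rate-limiting enzyme of melanin synthesis, the 5′ UTR peak (chromosome 7, 87493226 to 87493534) fell from 1.67 to 0.681 ± 0.238 CPM (−1.29, SE 0.34, adjusted p = 0.0449), and 3 of the 4 Tyr peaks fell. Tyrp1, encoding tyrosinase-related protein, had 7 falling and 0 rising peaks of 18. The strongest of them, intergenic and 5.8 kb upstream (chromosome 4, 80828051 to 80828770), went from 10.8 to 2.25 ± 0.037 CPM (−2.24, SE 0.20, adjusted p = 0.0125). The peak at the Tyrp1 5′ UTR gave −0.49 (SE 0.22, adjusted p = 0.164) and passed under the authors' scaling (−0.78, adjusted p = 0.0322); its value was −0.81 without hairpin I and −0.25 without hairpin II. An intergenic peak 77.7 kb from Slc24a5, a melanosomal cation exchanger, fell 7.64-fold, and one 3.47 kb upstream of Oca2, a melanosomal chloride channel, fell 1.88-fold. Against this trend, an intronic peak 32.2 kb from the Tpcn2 TSS rose from 0.598 to 4.30 ± 1.32 CPM. Slc24a5 had 3 falling and 0 rising peaks of 9, and Oca2 1 and 1 of 7. Tpcn2 had 2 falling and 2 rising peaks of 7, and Dct 2 and 0 of 5. The Tyr 5′ UTR peak no longer passed with cyclic loess offsets (−0.77, edgeR adjusted p = 0.155) or in the DESeq2 Wald test (−1.36, adjusted p = 0.348). With the controls as 1 sample it also did not pass by the newer quasi-likelihood estimate (adjusted p = 0.0643) or the likelihood ratio test (adjusted p = 0.121).

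**Figure D3:**
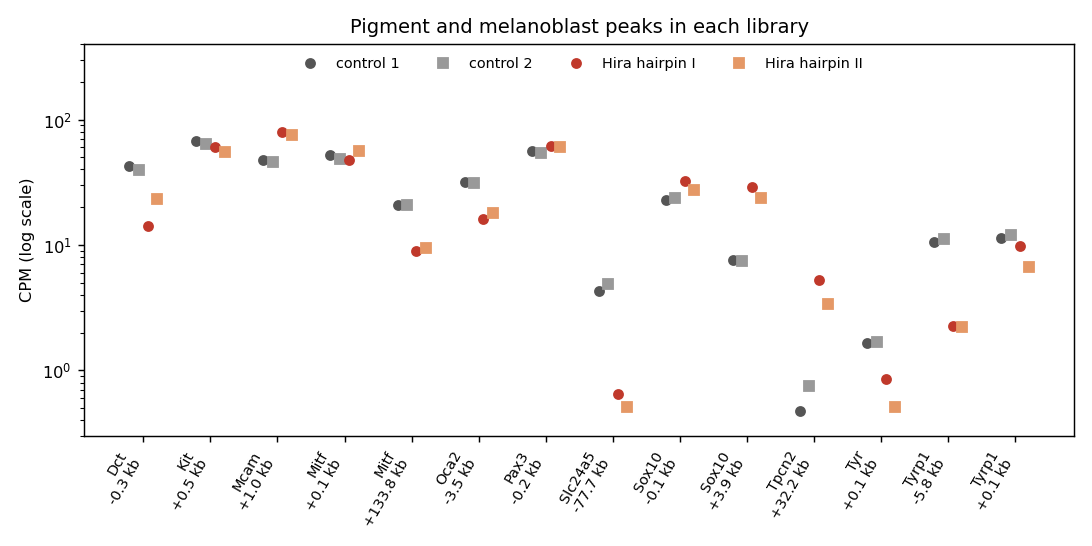
CPM (log axis) in each of the 4 libraries at the named pigment and melanoblast peaks, with the distance to the TSS under each gene. Grey symbols are the controls, which nearly coincide, and red and orange symbols are hairpins I and II. At the Tyrp1 peak 5.8 kb upstream both hairpins lie near 2.25, below the controls at 10.8.

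Genes of melanoblast specification and survival moved both ways. Of 230 peaks 48 fell and 28 rose (54 and 31 adjusted over the list alone). The list did not pass its test (camera, adjusted p = 0.114, and 0.586 with an estimated correlation). Its mean log2 difference from other peaks was −0.193, with −0.27 without hairpin II and −0.112 without hairpin I. The difference turned upward with promoter peaks alone (0.07) and with 1 peak per gene (0.025). Kit, the receptor for stem cell factor, had 10 falling and 3 rising peaks of 24. Mitf had 9 falling and 3 rising of 37, and Pax3 5 falling and 1 rising of 18. An intergenic peak 134 kb from the assigned Mitf TSS (chromosome 6, 98125174 to 98126028) fell from 20.9 to 9.18 ± 0.399 CPM (log2 fold change −1.19, SE 0.13, adjusted p = 0.0125). In contrast, a peak in an intron of Sox10, the neural crest transcription factor, 3.88 kb from its TSS (chromosome 15, 79160384 to 79160829), rose from 7.56 to 26.4 ± 3.81 CPM (1.81, SE 0.16, adjusted p = 0.0125). An intronic Mcam peak (Mcam encodes a cell adhesion molecule) rose 1.67-fold, a call lost under the authors' scaling (adjusted p = 0.161). A peak 25.5 kb from Rb1cc1, an autophagy gene, fell from 1.86 to 0.244 ± 0.0575 CPM.

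More peaks of neural crest progenitor genes rose than fell. Of 102 peaks 29 rose and 3 fell (32 and 5 adjusted over the list alone). The list lay above other peaks by a mean log2 of 0.31 (camera, adjusted p = 0.0206). The camera adjusted p was 0.331 with an estimated correlation, 0.0534 with promoter peaks alone and 0.00698 with 1 peak per gene. The mean log2 difference was 0.317 without hairpin II and 0.301 without hairpin I. Snai1, a repressor that drives epithelial to mesenchymal transition, had 5 rising and 0 falling peaks of 8. A Snai1 peak in an L1 repeat, 15.0 kb downstream of its TSS (chromosome 2, 167552726 to 167553605), rose from 0.502 to 7.91 ± 3.52 CPM (log2 fold change 4.01, SE 0.47, adjusted p = 0.0125). Peaks near Id2, an inhibitor of differentiation (1.83, SE 0.13), Nes, encoding the intermediate filament nestin (0.98, SE 0.08), and Ets1, a transcription factor (2.71, SE 0.30), rose with the same adjusted p.

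The extracellular matrix and migration list showed the highest share of rising peaks among the 20 lists. Of its 200 peaks 63 rose and 14 fell (69 and 17 adjusted over the list alone). The camera test gave an adjusted p of 0.0206, 0.331 with an estimated correlation and 0.00128 with 1 peak per gene. The list lay above other peaks by a mean log2 of 0.37, by 0.18 with promoter peaks alone and by 0.40 with 1 peak per gene. Fibroblast and dermal mesenchyme markers were close behind, with 30.2% of peaks rising against 31.5% and a mean log2 difference from other peaks of 0.33 against 0.37. A peak 116 kb from the TSS of Ccn2, which encodes a matricellular growth factor, went from 1.18 to 10.4 ± 1.94 CPM (log2 fold change 3.14, SE 0.28, adjusted p = 0.0125), and 10 of its 23 peaks rose while 4 fell. Collagen genes were represented by a peak 27.8 kb from Col5a1 (29.1 against 54.7 ± 1.17 CPM) and a peak 48.7 kb upstream of the Col4a2 TSS (4.34 against 14.6 ± 0.715 CPM). A peak 36.5 kb from Col1a2 went the other way, from 3.80 to 0.307 ± 0.0497 CPM (−3.63, SE 0.33, adjusted p = 0.0125).

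Senescence and p53 target genes had 25 rising and 8 falling peaks of 100 (27 and 9 adjusted over the list alone). The list passed its test (camera, adjusted p = 0.0323), but not with an estimated correlation (0.331), promoter peaks alone (0.115) or 1 peak per gene (0.355). Its mean log2 difference from other peaks was 0.281, with 0.159 on promoter peaks alone and 0.028 with 1 peak per gene. Peaks near the p53 targets Phlda3 (log2 fold change 1.27, SE 0.13), Gdf15 (1.04, SE 0.14) and Sesn2 (1.72, SE 0.24) rose, the Gdf15 peak with an adjusted p of 0.053 in the likelihood ratio test with the controls as 1 sample. As given above, no peak of Cdkn1a or Cdkn2a passed with 4 libraries.

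The other lists did not pass with 4 libraries and the preset correlation. HOX genes had 7 rising and 0 falling of 31 peaks (camera, adjusted p = 0.0557; 0.0451 without hairpin II, 0.238 without hairpin I) and inflammatory secretory genes 26 rising and 11 falling of 93 (0.0557). The inflammatory list passed with the controls as 1 sample (camera, adjusted p = 0.0193), with total tags (0.0485), with the authors' scaling (0.0396), and without control 1 (0.0258), control 2 (0.0216) or hairpin II (0.00664). It did not pass without hairpin I (camera, adjusted p = 0.176, mean log2 difference 0.20 against 0.35), with an estimated correlation (0.62), with 1 peak per gene (0.0936) or on promoter peaks (0.487). Adjusted p-values were 0.666 for stem cell quiescence and niche response, 0.375 for the cell cycle, 0.347 for the interferon response (0.0452 with promoter peaks alone), 0.877 for oxidative stress, 0.388 for AP-1 and immediate early genes, 0.717 for the HIRA complex and H3.3 deposition, 0.985 for Wnt signalling and 0.414 for ribosomal proteins. Among markers of other cell types, fibroblast genes had 19 rising and 6 falling of 63 peaks and Schwann cell and glia genes 6 rising and 11 falling of 84, each with an adjusted p of 0.114. The fibroblast list passed with the authors' scaling (camera, adjusted p = 0.0396), without control 1 (0.0425), without hairpin II (0.0434) and on its 3 promoter peaks (0.0429), but not without hairpin I (0.212), with the controls as 1 sample (0.0863), with 1 peak per gene (0.1) or with an estimated correlation (0.586). Keratinocyte, neuron and haematopoietic markers each had an adjusted p of 0.414. The oxidative stress list had a mean log2 difference from other peaks of −0.04, while its own mean and median and the direction of its test were upward.

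**Figure D4:**
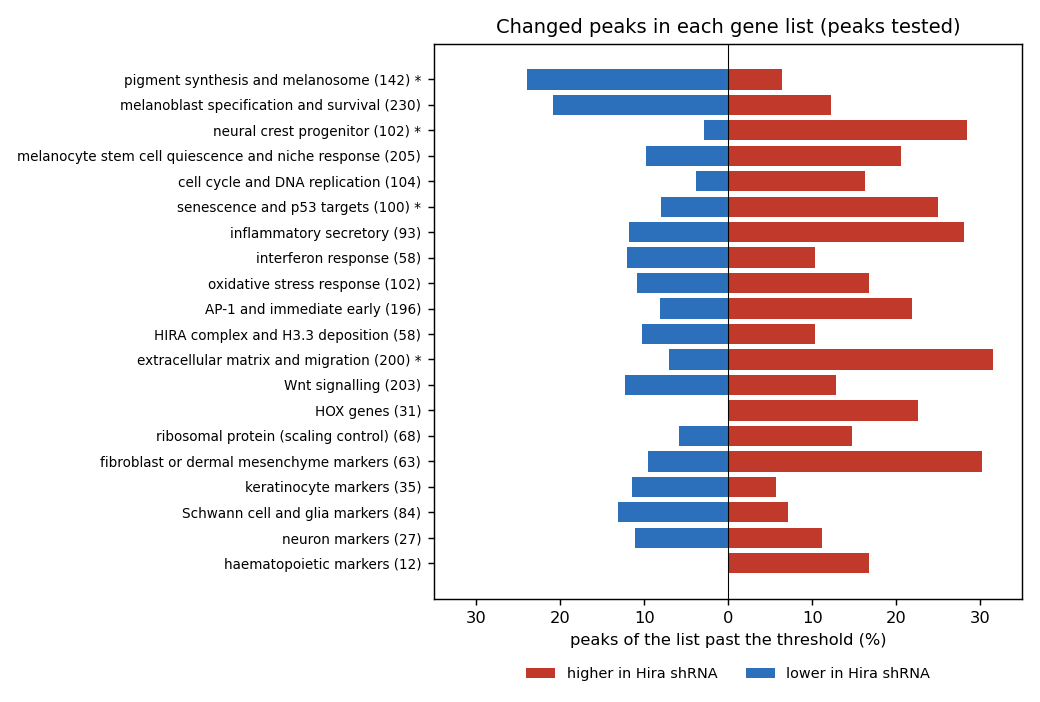
Percent of tested peaks of each gene list that were higher (red, to the right) or lower (blue, to the left) in Hira shRNA, with the number of peaks in brackets and an asterisk where the camera test had an adjusted p under 0.05 with the preset correlation. Pigment peaks lean to the left (23.9% lower, 6.34% higher) and matrix peaks to the right (31.5% higher, 7% lower).

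Peaks named for the size of their change had to lie above the median in mean abundance over all 4 libraries. A peak near background in 1 arm therefore passed only if it was high in the other. Within this limit, predicted genes left out, the largest gains were from near background to over 12 CPM. They included a site 21.5 kb upstream of the Lrrc10 TSS (chromosome 10, 117023631 to 117024008), with 0.828 against 13.4 ± 5.24 CPM (log2 fold change 4.00, SE 0.37, edgeR adjusted p = 0.0125). Another was the promoter of Ankrd23, a muscle ankyrin repeat gene (0.951 against 12.6 ± 4.21 CPM). Further gains lay near Sik1, Glt1d1, Hlcs, Actn1, which encodes an actin cross-linker, Nectin4, Micalcl and Slc38a2, with log2 fold changes between 3.56 and 3.91. At the Glt1d1 peak the hairpins differed most, with log2 ratios of 4.41 and 1.64, and the call was lost in limma-voom (adjusted p = 0.073). Within the same limits the largest losses were an intergenic site 62.6 kb from Sst (chromosome 16, 23828026 to 23828492; 16.0 against 1.73 ± 0.674 CPM, −3.15, SE 0.26, adjusted p = 0.0125) and an intronic site of Chmp4b (12.5 against 1.55 ± 0.225 CPM). Others lay near Plaat1, Ranbp3, Mx1, Drd4, Mapt, Epc2, Cd80 and Nkx6-2, with log2 fold changes between −2.89 and −2.70. Genes are those the authors' annotation assigned by the nearest TSS, and accessibility is not expression.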

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

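Tests with the controls as 1 sample, with the authors' scaling, with the newer quasi-likelihood estimate, without rounding and with a replicate block were chosen after the result was seen. Counts of changed, higher and lower peaks stayed within 1.5 times 17840, 10127 and 7713 under both other size factors, loess offsets, both filters, autosomes alone, the likelihood ratio test on 4 libraries, limma-voom, a log2 minimum of 1, the newer estimate and unrounded tags. The exceptions follow. DESeq2 called 4948 peaks lower, and the authors' scaling 13382. An adjusted p under 0.01 left 0 changed peaks (0 higher, 0 lower) in the quasi-likelihood test, where the smallest value was 0.0125, although 28282 peaks had an unadjusted p under 0.05 and the likelihood ratio test called 24092 at 0.05. With the controls as 1 sample, counts were 0 (0 higher, 0 lower) by quasi-likelihood, 9919 (5940 and 3979) by the newer estimate and 8558 (5291 and 3267) by the likelihood ratio test. Without 1 library at a time, changed peaks ranged from 0 to 42998, higher from 0 to 21795 and lower from 0 to 21203. The zeros came without either control, when the residual spread is that of the Hira pair alone and the lone control is assumed to vary like it. The highest came without hairpin II, when it is that of the control pair.

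The median log2 fold change over all peaks, 0.0019, was −0.0045 with DESeq2 size factors, −0.0208 with total tags, 0.0088 with loess offsets, −0.26 with the authors' scaling, and −0.0029 to 0.0049 without 1 library. The odds ratio for direction in promoter against other peaks was 1.04 with total tags and 0.601 to 1.59 without 1 Hira library, below 1 without hairpin II. It had no value where 0 peaks passed. The cause was not tested.

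With an estimated correlation 0 lists passed (pigment list at a mean log2 difference of −0.428), and with 1 peak per gene 2 lists passed (pigment list at −0.281). Without 1 library 4 to 7 lists passed. The pigment list kept its direction and its call under the other settings run for lists, with promoter peaks alone and the authors' scaling among them. No named peak that passed changed sign under any setting. All 42 of them lost their call in the quasi-likelihood test with the controls as 1 sample, and likewise without control 1 or without control 2. In the likelihood ratio test with the controls as 1 sample 2 did. Of the 9 named peaks that did not pass, 4 passed without hairpin II and 3 without hairpin I, where the control pair alone gives the spread. The columns number the libraries 1 and 2 in both arms, but nothing shows these numbers to be a pairing, and deviations of libraries with the same number from their group means had a correlation of −0.00725 across peaks. With the numbers as a replicate block the quasi-likelihood test called 18946 peaks (10275 higher, 8671 lower), the median log2 fold change was −0.0035, 5 lists passed, with the inflammatory list added, and the Tyr 5′ UTR peak alone of the 42 no longer passed (adjusted p = 0.0526). The motif tests and their alternatives were not run, for want of a genome sequence, and the alternatives for normalized values or for a table without counts did not apply.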

Other observations

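Of the tests in this part, those of gene neighbourhoods, adjacent peaks, B2 against Alu repeats, older B2 copies and mixed cells under hairpin II were chosen only after the result was seen. Gains clustered around some genes. Of 2235 genes with at least 8 peaks, 7 held more rising peaks than chance and 4 more falling peaks (one-sided hypergeometric test over exchangeable peaks, adjusted over both directions). Sorbs2, which encodes an adaptor of the actin cytoskeleton, had 17 rising and 2 falling peaks of 26 (adjusted p = 8.96e-06, median log2 fold change 1.29). Dusp10, a phosphatase of stress kinases, had 10 rising of 15 (adjusted p = 0.00649), Fam43a 12 of 23 (0.0198) and Flt1, a receptor for vascular endothelial growth factor, 10 of 18 (0.0348). Kit was the only gene of the fixed lists among them, with 10 falling peaks of 24 (0.0458). The test did not take the distance of peaks to the TSS into account. The share of falling peaks was 2.14% within 1 kb and 17.0% beyond 100 kb. The neighbourhood with the lowest adjusted p in this test was that of the predicted gene Gm20125 on chromosome 10, between 16473910 and 17385820. It held 32 rising and 4 falling peaks of 58 (2.18e-09, median log2 fold change 0.73). Neighbouring peaks are not independent: where 2 adjacent peaks under 10 kb apart both changed, 68.8% of 2396 pairs went the same way. The share was 57.6% of 523 pairs 50 to 200 kb apart and 59.4% of 106 pairs over 200 kb apart.

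Promoter peaks changed less often than others, with a ratio of the shares of 3.94 (others over promoters, 95% bootstrap interval over chromosomes 3.61 to 4.34). CpG islands outside the promoter class changed in 6.23% of 1767 cases, with 95 rising and 15 falling. Depth does not account for it: within deciles of mean log2 CPM the ratio was 3.44 (3.08 to 3.81). Width does not either, with a ratio of 3.69 (3.39 to 4.09) within 5 bins of peak width. Under the authors' scaling it was 6.97 (6.09 to 7.79). This does not decide whether the scaling is anchored on promoters. That scaling used 1.33 and 1.08 times the tags in peaks for hairpins I and II, and 0.97 and 1.07 for controls 1 and 2. It therefore also shifted the libraries within each arm against each other. How this changed the spread that the test uses was not measured. The SDs of log2 fold changes, 0.38 in promoter peaks and 0.97 elsewhere, would not change under a shift common to all peaks. A candidate explanation is that distal elements depend more on HIRA than promoters do, a hypothesis these libraries cannot separate from later changes of cell state. Profiles of HIRA and H3.3 at both kinds of peak, or accessibility soon after the loss of HIRA, would test it.

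Peaks in SINE B2 repeats seldom changed. Of 1457 such peaks 8.03% changed, against 30.3% of 697 peaks in Alu (B1) repeats (odds ratio 0.201, 95% interval 0.155 to 0.26, two-sided Fisher's exact test across peaks, p = 2.03e-38). Within 5 bins of mean log2 CPM the odds ratio was 0.264 (0.205 to 0.34) and within classes of distance to the TSS 0.2 (0.156 to 0.257), which argues against depth and position. Averaging of reads over near-identical copies stays open: the share changed was 2.9 times higher in the 485 widest than in the 484 narrowest B2 peaks (Alu peaks, 1.07), as averaging would give, since wide peaks hold more unique sequence, and the prediction written beforehand had that direction wrong. Against it as the whole source, the older and more diverged B3 and B3A copies gave an odds ratio of 0.221 (0.165 to 0.295) against Alu. B2 copies are known to carry binding sites of the insulator protein CTCF in mouse, so stable CTCF sites may be behind the pattern, which was not tested here.

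Hairpin II gave smaller changes than hairpin I. Its lower depth does not explain this, since hairpin I thinned to the tags of hairpin II still had an SD of log2 ratios 0.294 above that of hairpin II. On the linear scale, among peaks chosen by hairpin I against control 1 and read in hairpin II against control 2, hairpin II showed 0.509 of the change of hairpin I at 2809 gained peaks and 0.571 at 3409 lost peaks. The shares differed by 0.0619 (0.0366 to 0.0866), where a mixture with cells like the controls needs equal shares. This decides nothing, since the peaks were chosen by the hairpin I change that the shares divide by. Mixed cells and a weaker knockdown in every cell cannot be told apart here. No measurement of HIRA was used, so the larger changes under hairpin I need not reflect a stronger loss of HIRA.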
